A study of Arabidopsis arenosa with 6 samples.

How the data were processed

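RNA of Arabidopsis arenosa, a wild relative of the model plant Arabidopsis thaliana, was labelled with 1 dye (Cy3) and hybridised to 6 Agilent arrays designed for Arabidopsis genes. Per the labels' protocols, seedlings were inoculated in vitro 10 days after germination or left uninoculated, and grew for 28 days in pots, to an age of 38 days. Each sample was RNA of 3 plants, of which 0.5 µg was labelled. The tissue label and the design text say root, whereas the extraction protocol speaks of ground leaves. The text below follows the tissue label, and which organ was sampled was not settled from the sources used here. The 3 groups, taken from the sample titles, had 2 arrays each, and the labels do not say whether the arrays of a group came from separate extractions. The p-values then measure only the spread between these hybridisations, which may be technical.

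The deposited scanner tables hold 1 row per spot, made with Agilent Feature Extraction 10.7.3.1 per the file headers. Their intensity values are on a linear scale, and the column used here is the processed signal, from which the software had subtracted background and trends across the array, with small positive values in place of signals at or below background, per the file headers. Values near the low end therefore have no reliable order. The scanner tables also hold flags for spots well above background, saturated spots and outliers, set by the same software. A deposited table of the whole series holds log2 values, whose making is not given in the sources used here. Its 6 columns were matched to the arrays by name, and 0 columns stayed unmatched. Over 14029 rows of a single probe, differences between its columns had a slope and a Pearson correlation of 1 against the log2 processed signal. Its direction and scale were thus settled, and its columns lay within 0.05 log2 of a 75th percentile scaling. A constant subtracted from each row stays unknown, since the median over the arrays was within 0.001 of 0 in only 2728 of 33301 rows. The column medians of that table were 0.02 and -0.02 for control soil, 0.00 and -0.03 for uninoculated mine substrate, and 0.10 and 0.08 for the inoculated plants.

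The choices of this paragraph were made before the data were examined. The main values are log2 of the processed signal minus each array's 75th percentile of it over the 43803 spots that are not controls. Outlier spots were left out, spots of 1 probe were averaged, and 34 of 43603 probes were left out because a flag removed them on at least 1 array. A probe was kept if it was well above background on both arrays of at least 1 group, which left 30670 probes. A gene with several kept probes, as 5745 had, was represented by the one with the highest mean signal. The 3 groups were fitted together with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 3 residual degrees of freedom and 1.57 prior degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05.

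The files identify probes by the maker's probe number, a sequence accession and, through the table of the whole series, a numeric Entrez gene ID. They do not pair these with gene symbols or locus names, and no table of names was used here. Probes sharing an Entrez ID were taken as 1 gene, and other probes were grouped by accession or stood alone, which gave 23141 tested genes, 20377 of them with an Entrez ID. A set of 29 gene lists with 633 loci had been fixed in advance, and 0 of the loci could be matched, so no list was tested. The rule that was to choose named genes asked for a symbol or locus name and chose none. In its place, the gene with the largest fitted rise and that with the largest fitted fall are given by Entrez ID for the soil comparison and for the inoculation, among called genes with such an ID whose groups do not overlap. Each of these 4 was not well above background in 1 of the groups compared, where values have no reliable order, so the choice does not rank true changes, and some genes without an Entrez ID had larger fitted changes. That replacement was made after the files were seen. A fold against a group in which neither array was well above background is given as a lower bound. It sets the bright group's mean against the dim group's mean of the higher of the dimmest signal well above background and the probe's own signal on each array. The bound is nominal, since the true signal of a probe not well above background may lie above that dimmest one. An adjusted p printed beside a bound tests the fitted change and not the bound. The SD of a dim group may rest on values put in place of signals at background.

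Per the slide and scan entries of the file headers, the 4 uninoculated arrays lay on slide 1 in scan 1, and both inoculated arrays lay on slide 2 in scan 2. Slide and inoculation can therefore not be told apart. The soil comparison lies within slide 1, with control soil at array positions 1 and 2 and uninoculated mine substrate at positions 3 and 4. Within slide 1, soil can therefore not be told apart from position. The inoculated arrays lay at positions 1 and 2 of slide 2, as control soil did on slide 1. A position effect would thus enter the substrate and Mucor comparisons with opposite signs. Probes were designed for A. thaliana sequences, and a sequence difference in A. arenosa can change a probe's signal. Levels of different probes were therefore not set against each other.

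The limma step was tested on simulated arrays with the gene means and spreads of the real fit and 200 changed genes for each factor, among 23141 genes. For the soil comparison it called 66 of 71 genes changed 2-fold and 69 of 70 changed 4-fold, in the right direction, with 11 unchanged genes called. For the inoculation it called 55 of 62 genes changed 2-fold and 68 of 69 changed 4-fold, with 9 unchanged genes called. For inoculated mine plants against control soil it called 125 of 133 genes changed 2-fold and 137 of 139 changed 4-fold, with 22 unchanged genes called. These counts hold for normal noise drawn from the fitted spreads and for few changed genes. Scaling, the filter on dim probes and the choice of probe were not part of the simulated arrays. The number of arrays limits the precision. The alternatives covered quantile normalization, median scaling, the filter on dim probes, the probe rule, the samples in the fit, the variance model, a fold threshold, the deposited table of the series, the replicate number as a block and leaving out each array. Alternatives added after the data were seen are named as such in the closing section, and fold counts limited to genes well above background on all arrays compared were also added then. Figures were drawn with Matplotlib 3.10.9 in Python 3.11.15.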

Results

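Gene expression was profiled in Arabidopsis arenosa grown in 3 settings, with 2 arrays per setting. Control plants grew uninoculated in commercial soil mixed with sand. The others grew in substrate from a mine dump polluted with zinc, cadmium, iron and lead, either uninoculated or inoculated with Mucor sp., a fungus living inside the plant. Of the 43803 probe spots, 67.5% and 67.8% were well above background on the control soil arrays. The shares were 69.4% and 70.3% for uninoculated mine substrate and 66.5% and 67.7% for inoculated mine substrate. No spot was saturated, with 0 on each of the 6 arrays.

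Arrays of a group were much closer to each other than to other groups. Over the 23141 tested genes, which are not independent replicates, Pearson's correlation was 0.997 between the control soil arrays. It was 0.996 between the uninoculated mine arrays and 0.995 between the inoculated ones. Correlations ranged from 0.933 to 0.934 between control soil and uninoculated mine arrays, and from 0.979 to 0.980 between uninoculated and inoculated mine arrays. Between control soil and inoculated mine arrays they ranged from 0.935 to 0.937. The first principal component held 77.4% of the variance and set control soil apart from both mine groups. The second held 16.9% and set inoculated from uninoculated mine plants.

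**Figure D1:**
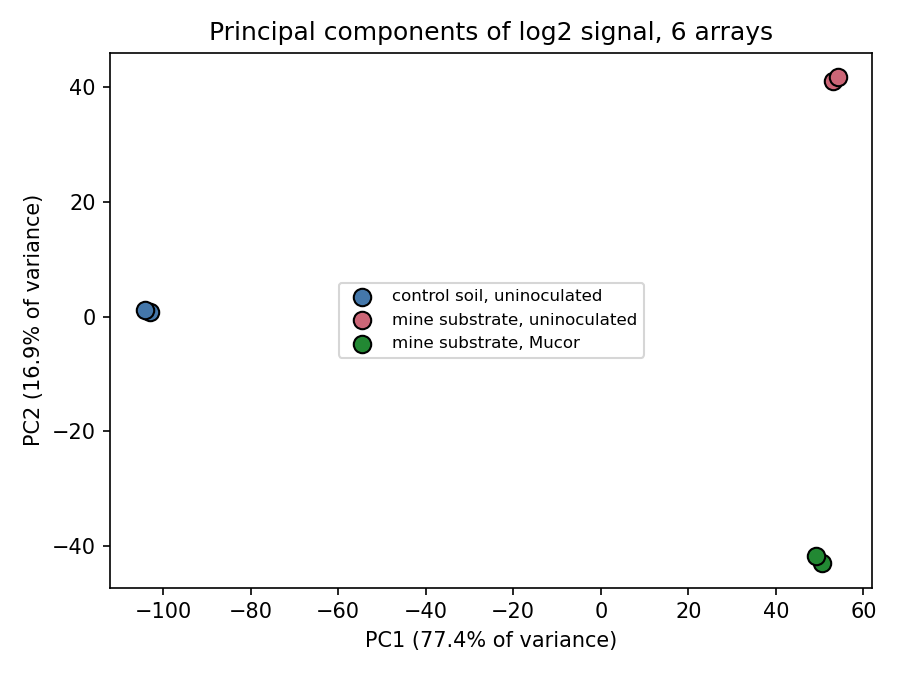
Scores of the 6 arrays on the first and second principal components of log2 signal (arbitrary units), coloured by group. The 2 arrays of each group lie together, control soil lies apart from mine substrate on the first component (77.4% of variance), and inoculated from uninoculated mine plants on the second (16.9%).

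The effect of the polluted substrate was addressed by comparing uninoculated plants of the mine substrate with those of control soil. Most genes differed: 10005 were higher and 8188 lower on mine substrate, together 78.6% of those tested. A fitted change of at least 2-fold was seen for 2664 genes that were higher and 2115 that were lower, and of 4-fold for 743 and 642. Among the 21319 genes well above background on all 4 arrays compared, the numbers were 1862 and 1733 at 2-fold, and 286 and 383 at 4-fold. Gene 822700 was chosen for its fitted fall, which ranks against a signal at background and is no order of true changes. Its log2 signal against the 75th percentile went from 1.35 ± 0.02 (SD, n = 2) in control soil to -7.70 ± 0.07 (SD, n = 2), where neither array was well above background. The signal was at least 265-fold lower (limma, adjusted p = 2.4e-06). Gene 828313, chosen likewise for its fitted rise, went from -6.80 ± 0.12 (SD, n = 2), not well above background, to 0.85 ± 0.06 (SD, n = 2), at least 176-fold higher (limma, adjusted p = 4.4e-06). These bounds are nominal and hold for the processed signal by the rule above, and the p-values test the fitted changes and not the bounds. With normexp and its offset of 50, the log2 changes were -5.38 for gene 822700 and 5.11 for gene 828313, beside log2 bounds of 8.05 and 7.46 in size.

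A further view of this comparison comes from genes measured on one side only. Of the called genes, 775 were well above background on both mine arrays and on neither control soil array, and 303 showed the converse. The change was at least 4-fold, taken as a bound, for 167 and 100 of them. The test was limma on all 6 arrays. With the 4 arrays of slide 1 alone, which hold both groups, 18429 genes were called. Position on that slide went with soil and cannot be told apart from it within the slide. The comparison of inoculated mine plants with control soil, given below, bears on this. For 91.4% of tested genes the arrays of the groups did not overlap, where chance gives 33.3%. Of 4697 called genes with other kept probes, 78.5% had all probes changed in the same direction, and of 826 called genes with a 2-fold change 88.4% did. The direction of small changes depends on the scaling: with arrays scaled on spike-in RNA, 3967 genes were higher and 14305 lower, because all genes moved down alike and their median went from 0.08 to -0.43 log2. Of the 18193 calls, 12155 stayed called in the same direction and 2223 were called in the opposite one.

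**Figure D2:**
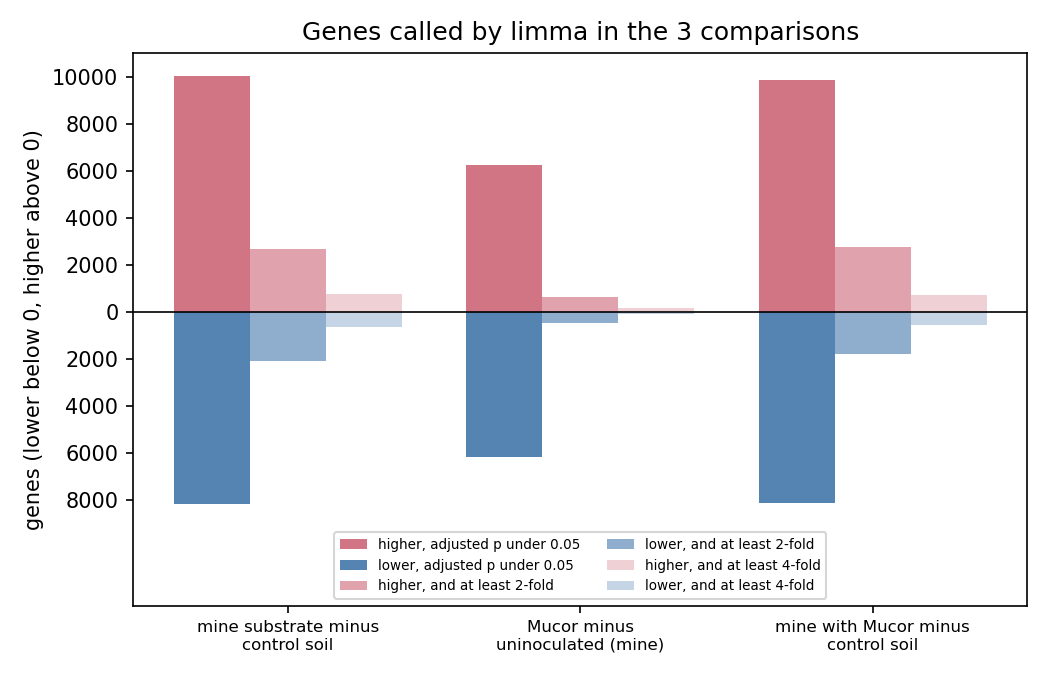
Number of genes called by limma (y axis, higher above 0 and lower below 0) in each of the 3 comparisons, for all calls and for those with a fitted change of at least 2-fold or 4-fold, genes at background in 1 group included. On mine substrate 10005 genes were higher and 8188 lower, and on the inoculated arrays 6220 and 6163. Inoculation cannot be told apart from slide and position, nor soil from position within slide 1. With spike-in scaling, the split is 3967 against 14305 for the substrate and 2063 against 13352 for the inoculation.

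The effect of the fungus was addressed by comparing inoculated with uninoculated plants, both on mine substrate. Calls covered 53.5% of the tested genes, 6220 higher and 6163 lower with Mucor, but most changes were small. The median absolute log2 change of called genes was 0.35, against 0.60 for the soils. A fitted change of at least 2-fold was seen for 640 genes that were higher and 473 that were lower, and of 4-fold for 155 and 108. Among the 21458 genes well above background on all 4 arrays compared, the numbers were 447 and 246 at 2-fold, and 60 and 25 at 4-fold. Gene 819102 was chosen for its fitted rise, again against a signal at background. Its log2 signal went from -9.02 ± 0.05 (SD, n = 2) without the fungus, not well above background, to -1.91 ± 0.02 (SD, n = 2), at least 27.6-fold higher (limma, adjusted p = 6.8e-05). In control soil it was at -6.94 and -7.11 on the 2 arrays, near the low end, where values have no reliable order. Gene 6241349, chosen for its fitted fall to a signal not well above background, went from -2.71 ± 0.11 (SD, n = 2) to -7.85 ± 0.01 (SD, n = 2), at least 11.4-fold lower (limma, adjusted p = 8.7e-05). In control soil it stood at -8.41 and -8.56, also near the low end. Again the p-values test the fitted changes and not the bounds. With normexp, the log2 changes were 2.80 for gene 819102 and -1.31 for gene 6241349, beside log2 bounds of 4.79 and 3.52 in size.

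Among genes called with Mucor, 113 were well above background on both inoculated arrays and on neither uninoculated mine array, and 268 showed the converse. The arrays of the groups did not overlap for 78.3% of tested genes, where chance gives 33.3%. Of 3185 called genes with other kept probes, 69.3% had all probes changed in the same direction. The inoculated arrays lay on a slide and scan of their own, and at positions 1 and 2 against 3 and 4. Inoculation can therefore not be told apart from slide or position in any of these values. With spike-in scaling 2063 genes were higher and 13352 lower, the median of all genes moving from -0.003 to -0.29 log2. Of the 12383 calls, 8226 stayed called in the same direction and 187 were called in the opposite one. With each gene's error raised to at least the median SD of repeat spots on an array, 0.078 log2, 7222 genes were called.

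**Figure D3:**
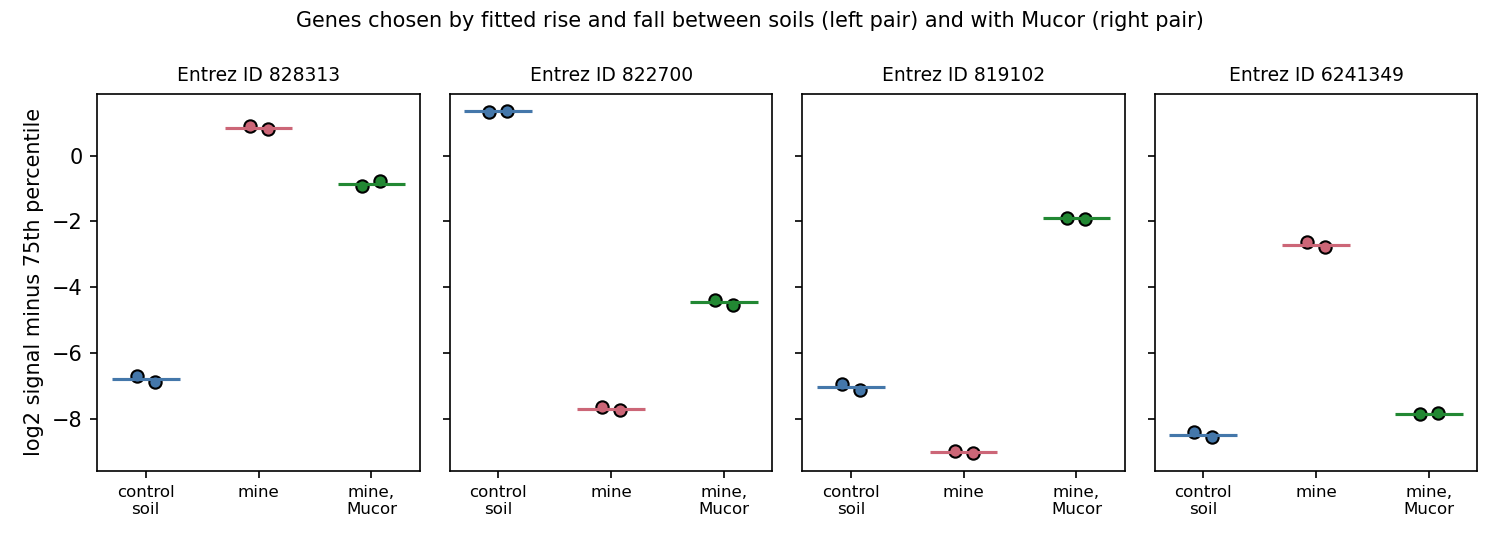
Log2 signal minus the array's 75th percentile (y axis) of 4 genes, given by Entrez ID, with points for the 2 arrays of each group and lines for their means. Genes 828313 and 822700 rose and fell between soils, genes 819102 and 6241349 rose and fell with Mucor, and the lower value in each of these changes is not well above background.

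The third pair of groups sets inoculated mine plants against uninoculated control soil plants, and crosses both factors and the slides. It gave 9869 genes higher and 8150 lower in inoculated mine plants, or 77.9% of those tested. A fitted 2-fold change was seen for 2750 and 1799 of them, of which 1990 and 1334 were well above background on all 4 arrays compared. Of the 18193 genes called between the soils, 14804 (81.4%) were also called here in the same direction, where independent lists would share 7151. Another 822 were called in the opposite direction and 2567 were not called. Both comparisons use the control soil arrays, which add a covariance of 0.02 to the observed 0.96 of their log2 changes. Slide and inoculation cannot be told apart here either. Both groups lay at array positions 1 and 2 of their slides, so position does not separate them. The 14804 calls shared in direction thus argue against position alone as the cause of those soil calls, unless the slide difference happens to follow it. With spike-in scaling 2426 genes were higher and 17352 lower, the median of all genes moving from 0.07 to -0.73 log2. Of the 18019 calls, 10576 stayed called in the same direction and 4766 were called in the opposite one.

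The design sets the changes with the fungus against those on the polluted substrate. Of the genes called in both comparisons, 7019 moved in opposite directions and 3365 in the same one. Independent lists would give 4865 and 4870. Genes higher on mine substrate and lower with Mucor numbered 3727, and genes lower on mine substrate and higher with Mucor 3292. At a 2-fold change in both, 255 genes rose on mine substrate and fell with Mucor, and 277 did the converse, where independent lists would give 54.5 and 58.5. Another 97 rose and 64 fell in both, where independent lists would give 73.7 and 43.2, so both kinds of overlap exceeded independence. Among the 20904 genes well above background on all 6 arrays, 102 and 176 moved in opposite directions at 2-fold, where independent lists would give 18.8 and 31.0, and 41 rose and 26 fell in both, beside 35.4 and 16.5. Gene 822700 is one of the 277: it was at 1.34 and 1.37 in control soil, -7.65 and -7.75 on mine substrate, and -4.39 and -4.53 with Mucor.

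Both comparisons use the uninoculated mine arrays with opposite sign, which alone gives opposite changes. In 100 simulations of unchanged groups sharing these arrays, 0 genes were called in both, a count that hardly any sharing could raise and that tells little about it. The covariance of the 2 log2 changes was -0.17 over all tested genes, beside -0.01 in the simulations. The correlation was -0.29 beside -0.50 in the simulations, and 60.8% of genes had opposite signs beside 66.7%. Sharing a group in noise alone sets these simulated correlations and shares, so they are no yardstick for data with many changed genes. With one uninoculated mine array used for the substrate change and the other for the Mucor change, the covariance was -0.16 and -0.15. It was -0.06 with normexp background correction and -0.10 over genes well above background on all 6 arrays. Neither the slide nor the array position can be told apart from the fungus in these values. With spike-in scaling, which shifts every gene of a comparison by the same amount, 4224 genes were called in opposite directions and the covariance was the same, -0.17.

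**Figure D4:**
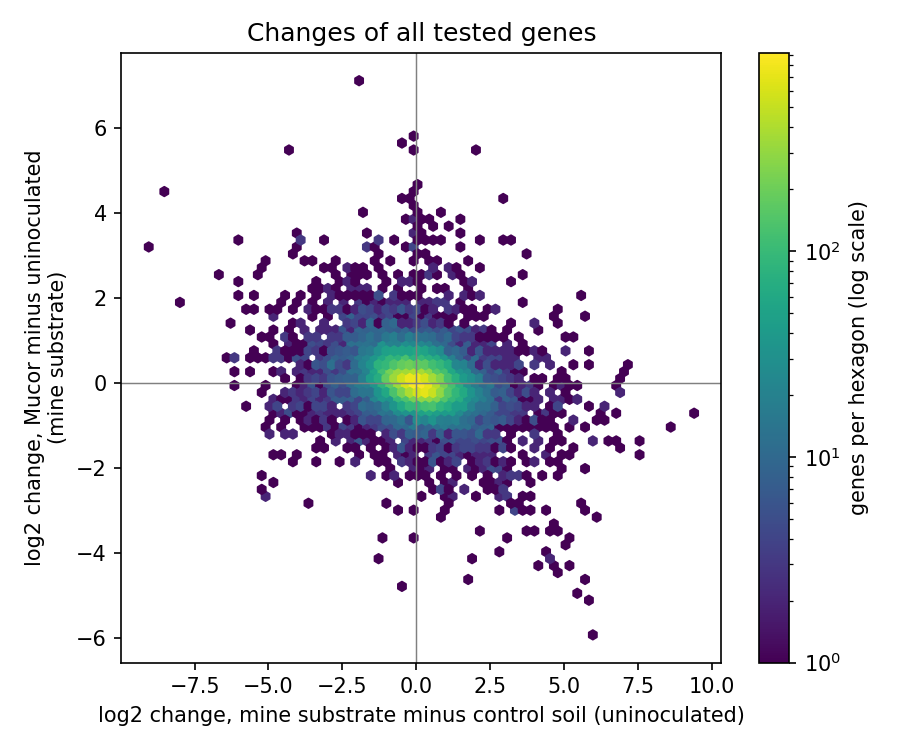
Log2 change between soils (x axis, mine substrate minus control soil, uninoculated) against log2 change with Mucor on mine substrate (y axis) for the 23141 tested genes, with colour for the number of genes per hexagon on a log scale. The cloud is wider along the soil axis (SD 1.06) than along the Mucor axis (SD 0.55) and tilts downward (covariance -0.17).

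Probe signal relative to spike-in RNA, which has its own control probes on the array and whose amounts are not given in the sources used here, differed between groups. The 75th percentile minus the mean log2 signal of 6 spike-in probes was -0.53 and -0.57 in control soil. It was -1.08 and -1.03 on uninoculated mine arrays and -1.30 and -1.39 on inoculated ones. The unscaled 75th percentile was 1573 and 1582 intensity units in control soil, 1113 and 1048 on mine substrate, and 838 and 941 with Mucor. With 2 arrays per group, the smallest p of a two-sided exact permutation test is 0.333, so that test could not pass 0.05 here, and no other test was run on these values.

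**Figure D5:**
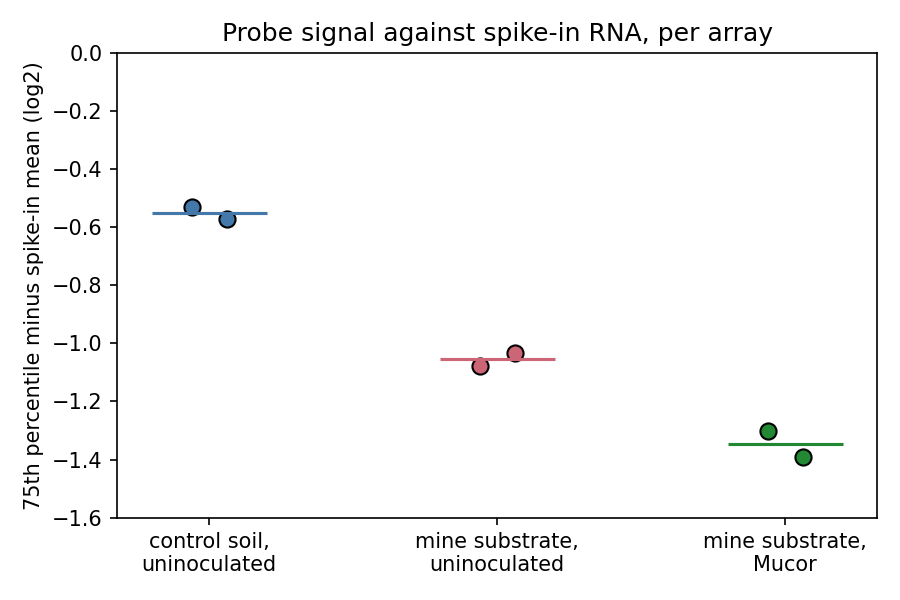
The 75th percentile of probe signal minus the mean signal of 6 spike-in probes (y axis, log2) on each array, with lines for the group means. Control soil arrays lie at -0.53 and -0.57, uninoculated mine arrays at -1.08 and -1.03, and inoculated arrays at -1.30 and -1.39.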

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

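Each result was computed again under every alternative that could be run. The counts of calls have no direction of their own, but spike-in scaling, which shifts all genes of a comparison alike, turned the majority from higher to lower in each comparison. It turned 2223 calls between soils, 187 with Mucor and 4766 for both factors, a number set by the size of the shift, which is under 2-fold and so turns no 2-fold change. With Mucor the split as reported was near even, and lower calls also outnumbered higher ones with quantile normalization (6381 against 6005), the deposited table (6455 against 5997), the mean of a gene's probes (6101 against 5809), each probe on its own (8332 against 7561), genes with several probes of the same sign (1195 against 1011) and without inoculated replicate 2 (5315 against 5213). The covariance stayed negative. Without a filter on dim probes, 9366 genes were higher with Mucor, against 6220 as reported. Requiring a 2-fold change left 4779 genes between soils, 1113 with Mucor, 4549 for both factors together and 532 in opposite directions. The following alternatives were chosen after seeing the data. Testing against a 2-fold change with limma's treat left 2771 between soils, 331 with Mucor and 2636 for both factors. Counting only genes with several kept probes of the same sign, far fewer genes by construction, left 3688, 2206 and 3365 in the same order. Raising each gene's error to that of repeat spots left 7222 with Mucor and 3951 in opposite directions, and spike-in scaling left 4224 in opposite directions, by its common shift of all genes. The covariance of the substrate and Mucor changes was -0.168 with quantile normalization, -0.193 with no filter on dim probes, -0.0979 over genes well above background on all arrays, -0.147 for each probe on its own and -0.167 from the deposited table. After seeing the data it was also computed with normexp on the median signals (-0.0569) and from separate mine arrays (-0.160 and -0.154). The cause of these moves was not tested. Leaving out 1 array at a time, which assumes that the lone array varies like the other groups, gave covariances from -0.193 to -0.169, 16199 to 18429 genes between soils, 9511 to 10528 with Mucor, 15747 to 17847 for both factors and 5330 to 6049 in opposite directions. Calls were higher for 63.0% of genes with Mucor without a filter on dim probes, and for 60.8% with normexp, against 50.2% as reported. The 4 genes given by ID kept their call and direction in all 64 of their alternatives, but not their size, which with normexp lay below the bounds given. Same-numbered arrays share only a number (correlations of deviations 0.04, -0.02 and 0.07), and the replicate block gave 17934, 11403 and 17699 calls and 6468 in opposite directions. Not run were the gene list tests, for lack of gene names, and normexp on mean signals, a column the scanner tables used here do not hold. Signal over background limits genes dim in 1 group to bounds.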

Other observations

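The tests in the weighing of patterns were chosen after the results were seen, except those of the trend on mean signal, of groups on both slides, of second replicates and of total signal, which were fixed before their values were known.

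Detection with the fungus was also counted for genes measured in 1 soil only. Of the 775 called genes well above background on both uninoculated mine arrays and on neither control soil array, 380 were so on both inoculated arrays and 266 on neither. Of the 303 called genes with the converse, 39 were above background on both inoculated arrays and 236 on neither. A group of 69 genes was above background on both inoculated arrays and on no uninoculated array of either soil. Both sets of called genes were picked by detection on the uninoculated mine arrays, so the counts are given as values and not as a test of the fungus, and the slide difference described above applies to them.

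Genes with consecutive Entrez ID numbers changed together somewhat more than shuffled genes. Over 15416 such pairs, Pearson's correlation of the soil changes was 0.072, and the largest absolute value in 100 shuffles was 0.023. Both members were called at least 4-fold in the same direction in 56 pairs, where shuffles gave 23.3 on average and at most 35. For the inoculation the correlation was 0.049, with 0.021 as the largest in 100 shuffles. Pairs are not independent of each other, and no probe sequences were used here.

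The first pattern weighed is that 78.6% of genes were called between soils. The spread between replicate arrays was small, with a robust SD per spot of 0.040 log2 in control soil, 0.067 on mine substrate and 0.071 with Mucor. Repeat spots on 1 array had a median SD of 0.078 over 9 probes with 5 spots each, and a root mean square SD of 0.123. On these probes the replicate spread was 0.047, 0.068 and 0.096. Over 6 bright spike-in probes with 32 spots each, repeat spots had a median SD of 0.048. Noise between spots does not account for the calls, since 87.8% of their number was left when each gene's error was raised to the larger of these, and scaling does not either, since 94.7% or more kept their call and direction under quantile normalization and median scaling, though 66.8% did with spike-in scaling. It also stays open whether both arrays of a group carried the same RNA, and then the calls would hold for these plants and not for the soils at large. On the same 9 probes the replicate spread was 0.60 times the repeat-spot spread in control soil, 0.87 on uninoculated mine substrate and 1.23 with Mucor. Separate pools of plants might also give such ratios. The replicate spread is a robust SD and the repeat-spot spread a median of SDs, so the ratios are rough.

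The second pattern is the opposite direction of substrate and Mucor changes. Hybridisation noise of the shared mine arrays does not account for it, because the covariance was still -0.154 with separate arrays, although any variation of the plants behind both mine arrays stays shared. A difference between slides that follows a gene's mean signal over all arrays does not account for it either, with a covariance of -0.171 after that trend was removed. Removing the trend cannot take out a difference acting on genes that are dim in only some groups. The covariance was -0.0569 with normexp and -0.0979 over genes well above background on all arrays, so a difference at low signal is not excluded. A candidate explanation is that inoculated plants were nearer to control soil plants. Of the 4872 genes 2-fold apart between first replicates, 66.2% lay nearer to control soil with Mucor than without in the second replicates. That share largely restates the pattern and is no separate test of it. Over all tested genes the shift was small, with a slope of -0.152 of the Mucor change on the substrate change. Correlations with control soil arrays were 0.935 to 0.937 for inoculated and 0.933 to 0.934 for uninoculated mine arrays. This explanation cannot be told apart from a slide difference specific to probes, since 0 groups had arrays on both slides. Nor can it be told apart from an effect of array position. The inoculated arrays lay at positions 1 and 2, as those of control soil did, and the uninoculated mine arrays at 3 and 4. A position effect would thus give opposite changes in the 2 comparisons.

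The third pattern is the lower probe signal against spike-in RNA. More spike-in RNA on the mine arrays is argued against by the spike-in signal itself, which was -0.0412 log2 from that of control soil, if the scanner settings of that slide were equal. Slide and scan do not account for the step of -0.51 between soils, which lies within 1 slide, but position on that slide cannot be told apart from soil. The share of the signal in the 100 brightest probes, 14.4% on average in control soil, was higher on mine substrate by 3.25 percentage points. That rise does not account for the whole step, since the total signal itself moved by -0.50. The further step of -0.29 with Mucor cannot be told apart from the slide. A lower share of plant messenger RNA in the labelled RNA, or a lower labelling yield, might give both steps and was not tested.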
